A study of Mus musculus with 41 samples.

How the data were processed

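RNA was measured in KH2 mouse embryonic stem cells from 12 groups: uninduced cells and cells kept in RA for 11 times from 2 to 72 h. Per the labels, uninduced cells grew at passage 12 on irradiated feeder cells in medium with 15% serum, and differentiating cells were in medium with 10% serum and 0.03 µM RA, with an RA supplement given as 33 nM (written nm); feeder cells were removed by letting them settle on gelatin. A vehicle control was not analysed here, so that RA, the change of serum and the loss of feeder contact are compared together. Per the labels' protocols, total RNA was amplified, labelled with the dye Cy3 and hybridised with 1 sample per array.

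The authors deposited 1 value table with log2-like ratios, 1 column per sample. Per the submitters' processing notes limma was used, with no version; the normalization, the reference, the log base and the direction of the ratio are not given in the sources used here. The 38 RA columns hold no missing value, run from -4.75 to 7.96 and are centred near 0, and the 3 uninduced columns are blank. The values were therefore taken as log2 ratios against the uninduced cells, each group mean was tested against 0, and that test leaves out the spread of the uninduced samples themselves. All times share that reference. Differences between RA times are free of it. Background and brightness of the spots cannot be read from ratios. Whole-number probe identifiers from 4 to 105068 carry no gene or position, and the table of gene names used here pairs no probe with a gene, so the probe was the feature and neighbouring probes of 1 transcript count separately.

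Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Arrays of the same time correlated over probes with a median of 0.557 and a range of -0.285 to 0.937, and no pair held the same values (highest correlation 0.952).

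One limma fit (version 3.58.1, R 4.3.3) of the 11 group means used all 38 arrays with 27 residual degrees of freedom and plain eBayes. Two-sided contrasts gave each time against 0, each of the 10 successive steps and 72 h against 24 h; a moderated F test gave changes at any time. Calls had an adjusted p under 0.05 (Benjamini-Hochberg within each contrast). A log ratio of at least 1 in size, a 2-fold difference, served as a second threshold. Replicates 4 to 6 were set against 1 to 3 in a limma fit of the 6 arrays of each time. Values in the text are group means with the SD between arrays; for a group of probes, each array's median over the probes was taken first. The first component of the deviations from the group means held 60.1% of their variance.

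The design, the alternatives and the rule for named probes were fixed before the data were examined. That rule asked for Hox genes and other named lists, the 8 highest and 8 lowest called features at 2, 6, 24 and 72 h with all arrays on 1 side of the reference, and the 4 features with the smallest p of the F test. With no names, at most 2 probes above and 2 below the reference were to be printed, and those with the smallest p of the F test on each side were taken; the extremes are given as ranges. At 6 h these ranged from 5 to 5.74 and from -1.3 to -2.53 (n = 2). The planned analyses by gene, of onset order along Hox clusters, of genomic windows and of gene lists were not run, because they need probe names or positions.

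The fit was tested on simulated data made from the spread of these arrays for all 103446 probes, with 100 probes changed by each size. The noise was drawn independently for each probe and array, with 1 spread per probe. Components shared by many probes and arrays broader than others, both present in the real data, were not simulated. The shares below therefore hold for independent arrays of equal quality only. For 72 h against the reference, 87% of changes of 1 and 98% of changes of 2 were recovered, with 3.65% false calls among the calls. That share was 5.83% for 24 h against the reference, 6.22% for the step from 24 h to 36 h, 4.57% for that from 36 h to 48 h and 5.26% for 72 h against 24 h. For the step from 36 h to 48 h the recovered shares were 74% and 93%, and for that from 24 h to 36 h they were 83% and 98%.

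Alternatives were a fit of each time alone, a replicate block, median centring, quantile normalization, eBayes with trend and robust options, the size threshold, array weights (limma, gene-by-gene method), either replicate set of 12 h and 24 h, and leaving out each array. Quantile normalization shifted array medians by -0.0687 to 0.174. It also gives every array the same distribution, where the SD over probes ran from 0.211 to 0.779 in the deposited values. Added after seeing the data were subtraction of the median of the neighbouring spots (2 lines of 199 spots and 3 spots to each side), leaving out the 2 broadest arrays or turning their sign, differences between RA times alone, both scalings for steps and for 72 h against 24 h, and further fits of either replicate set. The line length of 199 was the lag in probe number at which the mean log ratios of these arrays correlated most. That correlation was 0.126, against at most 0.0785 at lags not within 3 of its multiples.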

Results

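Transcript levels were followed over 72 h in KH2 cells, a mouse embryonic stem cell line, after transfer to medium with retinoic acid (RA), a vitamin A derivative that drives these cells towards neural fates. The series title asks how fast RNAs of the Hox clusters, the gene groups that pattern the body axis, respond. RNA was labelled with a single dye and hybridised to a custom tiling array, on which short probes step along genomic regions, so that several probes can report 1 transcript. The series holds 41 samples. The 3 uninduced samples have no values in the value table, and the 38 RA samples have a log ratio for each of 103446 probes. There were 3 arrays at 2, 4, 8, 16, 36, 48, 60 and 72 h, 2 at 6 h, and 6 at 12 and at 24 h. The number of arrays limits the precision, and the typical standard error of a mean log ratio was 0.11 with 3 arrays and 0.0774 with 6. These errors rest on 1 spread per probe pooled over all 11 times. The p-values below therefore do not measure the spread of the arrays at a single time. Fits of 1 time alone called 1905 probes in place of 38522 at 72 h and 18204 in place of 1704 at 8 h.

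The probes are known here only by number, with no gene or position, so that Hox genes could not be followed by name and groups of probes are described instead. Array medians lay between -0.193 and 0.05. The log base, the centring and the reference of the ratios are not stated; base 2 and the uninduced cells as the reference were assumed. The direction is not stated and no table used here tests it. Values above 0 are read as higher after RA by the usual convention of sample over reference; if the ratio runs the other way, each count of higher probes below is a count of lower ones and the totals stand. Among the 38 arrays, 4 pairs correlated below -0.3 over all probes, the lowest at -0.417, and each pair joined 24 h replicate 5 or 72 h replicate 2 with replicate 3 of 2 h or of 6 h. On the probes that stood highest, no array ran against the others. Over the 100 probes with the highest mean in the arrays of all other times, the median was above 0 in 38 of 38 arrays, between 0.923 and 5.33. At least 99% of these probes were above 0 in each array.

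The earliest samples ask which transcripts move within hours of RA. At 2 h, 149 probes were higher and 649 lower than the reference (limma, adjusted p under 0.05), but of those with a log ratio of at least 1 in size, 78 were higher and 10 lower. The 8 probes that stood farthest above the reference at 2 h had means of 4.58 to 5.45, a 24 to 43.6-fold difference. The numbers with a size of at least 1 grew to 235 higher and 51 lower at 4 h, 298 and 54 at 6 h, and 393 and 78 at 8 h. These numbers depended on the scaling: quantile normalization gave 340 higher and 187 lower at 2 h, 664 and 188 at 4 h, 733 and 315 at 6 h, and 881 and 76 at 8 h. Without regard to size, 374 higher and 820 lower probes were called at 4 h, 395 and 610 at 6 h, and 704 and 1000 at 8 h. After quantile normalization there were 1518 higher and 1359 lower at 2 h, 6542 and 2167 at 4 h, 1638 and 1279 at 6 h, and 8893 and 2520 at 8 h. The excess of lower probes did not hold under that scaling, which gave 52.8% higher among the calls at 2 h in place of 18.7%, 75.1% in place of 31.3% at 4 h, 56.2% in place of 39.3% at 6 h and 77.9% in place of 41.3% at 8 h. When the median of the neighbouring spots was subtracted (chosen after seeing the data), the shares were 36.9%, 55.7%, 64.3% and 66.6% at these times. There were 134 higher and 229 lower at 2 h, 428 and 340 at 4 h, 448 and 249 at 6 h, and 830 and 417 at 8 h. The totals of 798 at 2 h, 1005 at 6 h and 1704 at 8 h fell to 506 without replicate 1 of 2 h, to 391 or 371 without replicate 2 or 3 of 6 h, and to 992 without replicate 2 of 8 h. The split at 4 h also depended on single arrays. It was 735 higher and 577 lower without replicate 1, 653 and 643 without replicate 2, and 215 and 588 without replicate 3.

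Probe 55987 and probe 93109 had the smallest p of the test over all times among probes above the reference. Probe 55987 had a mean of 5.45 ± 0.37 (SD, n = 3) at 2 h, a 43.6-fold difference, 6.09 ± 0.88 (SD, n = 6) at 24 h and 5.85 ± 0.99 (SD, n = 3) at 72 h (limma, adjusted p = 1.08e-12, 2.01e-18 and 3.37e-14). Probe 93109 stood at 4.86 ± 0.27 (SD, n = 3), 5.52 ± 0.85 (SD, n = 6) and 5.25 ± 0.86 (SD, n = 3) at those times (limma, adjusted p = 1.2e-11, 2.3e-17 and 2.91e-13). The p-values rest on the pooled spread and not on these SDs. For probe 55987 the standard error was 0.32 at 2 h and at 72 h alike. Both probes were above 0 in 38 of 38 arrays and no difference between 24 h and 72 h was called for either (limma, adjusted p = 0.773 and 0.743). The test of differences between RA times alone called neither probe (limma's moderated F test, adjusted p = 0.437 and 0.46). The tests of these probes against 0 therefore cannot separate a change after RA from a constant offset of the reference. Among probes below the reference, probe 18923 stood at -2.55 ± 0.055 (SD, n = 3) at 2 h and -2.47 ± 0.18 (SD, n = 3) at 72 h, and probe 13378 at -0.97 ± 0.082 (SD, n = 3) and -0.85 ± 0.11 (SD, n = 3). These low values were nearly constant, with an SD over all 38 arrays of 0.0988 and 0.0869. Neither low probe was called between RA times (limma's moderated F test, adjusted p = 0.927 and 0.376), so that the same limit holds for them. When the median of the neighbouring spots was subtracted, probe 18923 at 24 h moved from -2.55 to -2.45 and probe 13378 from -0.99 to -0.25.

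**Figure D1:**
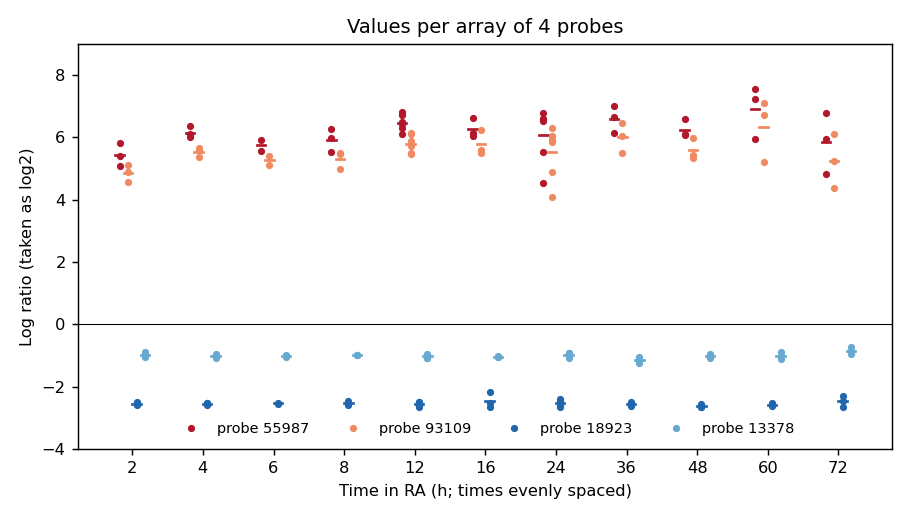
Log ratio (taken as log2, vertical axis) of 4 probes in each of the 38 RA arrays against time in RA in h; points are arrays and bars are group means. Probes 55987 and 93109 lie above 0 and probes 18923 and 13378 below 0 at all 11 times.

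From 12 h to 24 h, with all arrays in the fit, most of the probes called at least 2-fold from the reference were higher. With a size of at least 1, 771 were higher and 76 lower at 12 h, 483 and 159 at 16 h, and 902 and 202 at 24 h. After quantile normalization the lower ones were 350 at 12 h and 269 at 16 h. Without regard to size the calls were 3237 higher and 1431 lower at 12 h, 1181 and 1449 at 16 h, and 3268 and 2932 at 24 h. The means of the 8 highest probes at 24 h were 5.65 to 6.92 and those of the 8 lowest -2.77 to -2.93. Quantile normalization gave 9741 higher and 11800 lower at 12 h, 45.2% higher in place of 69.3%. Centring each array on its median gave 60.1% in place of 44.9% at 16 h, where neighbour subtraction gave 68.3%. The total of 2630 at 16 h was 1541 without replicate 1. That of 6200 at 24 h was 10565 without replicate 2, 4131 without replicate 6, 3338 with only replicates 1 to 3 and 42134 with only replicates 4 to 6. The direction moved too. At 16 h, 919 were higher and 838 lower without replicate 2. At 24 h more were lower without replicate 1, 2 (3895 higher and 6670 lower) or 3, and more higher without replicate 4, 5 or 6. With only replicates 4 to 6 of 24 h, 15675 were higher and 26459 lower, of which 1220 and 1303 had a size of at least 1.

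From 36 h to 60 h most probes called with a size of at least 1 were higher. There were 1514 higher and 293 lower at 36 h, 1421 and 299 at 48 h, and 1726 and 328 at 60 h (1002 higher at 36 h and 1058 at 60 h after quantile normalization), against totals of 6408, 5635 and 7527 without regard to size. At 72 h, 1380 were higher and 1202 lower by at least 1, within 13137 higher and 25385 lower in all. The means of the 8 highest probes at 72 h were 5.1 to 5.85 and those of the 8 lowest -3.84 to -4.07, a 14.3 to 16.8-fold difference. The count of 38522 at 72 h depended on single arrays and on the processing. It was 19684 without replicate 1, 12678 without replicate 2 and 52762 without replicate 3. It was 6430 after quantile normalization (692 higher and 257 lower by at least 1), 9900 with array weights and 1905 with the 72 h arrays alone in the fit. Without the 2 arrays of broadest values (24 h replicate 5 and 72 h replicate 2, an alternative chosen after seeing the data) it was 22034, with 1424 higher and 407 lower by at least 1. Leaving out replicate 3 of 36 h gave 3750, replicate 2 of 48 h 3662 and replicate 1 of 60 h 4242. The share of higher calls was 48.7% in place of 34.1% at 72 h after median centring and 50.6% after neighbour subtraction, and after quantile normalization 56.7% in place of 68.5% at 36 h, 50% in place of 67.5% at 48 h and 53.6% in place of 70.1% at 60 h.

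**Figure D2:**
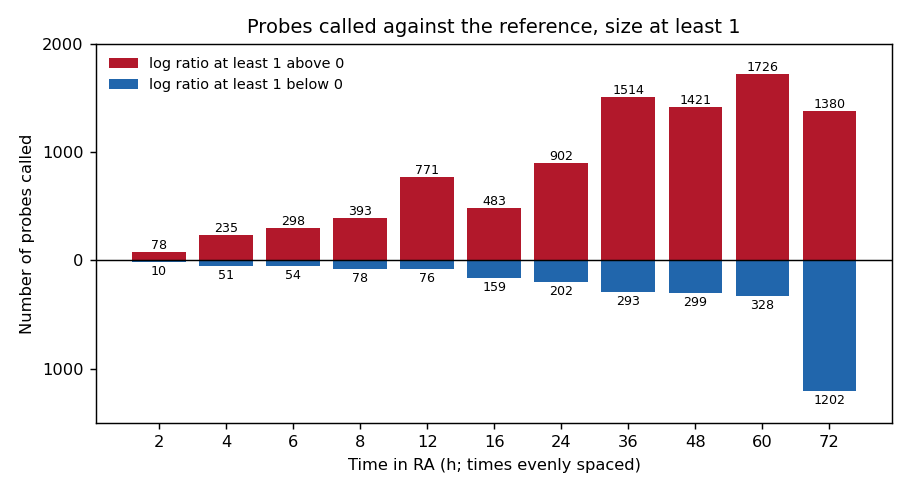
Number of probes called against the reference (limma, adjusted p under 0.05) with a log ratio of at least 1 in size, by time in RA in h; red bars count probes above the reference and blue bars probes below it. Higher probes go from 78 at 2 h to 1726 at 60 h, and lower probes from 10 at 2 h to 1202 at 72 h.

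Taken over all 11 times, 20518 probes (19.8%) differed from the reference at some time in limma's moderated F test. That test includes any offset of the reference itself. The test of differences between RA times alone called 4529 probes (4.38%), and 15989 of the 20518 were not among them. Without 24 h replicate 5, 32313 probes differed from the reference.

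Probes were then sorted by onset, the first time at which they were called with a size of at least 1 and were so again at the next time. Because the times share the reference, part of this persistence may come from it. Up to 60 h a held rise was found for 1608 probes, 385 of them by 8 h and 941 by 24 h, and a held fall for 335 probes, 73 by 8 h and 196 by 24 h. A further 308 rises and 879 falls were called with that size at 72 h, which has no next time, and had no held onset before. Without the 2 broadest arrays there were 1750 held rises and 334 held falls, and with the 72 h ones 432 falls in place of 1214. Rises began in 75 probes at 2 h, 152 at 4 h, 50 at 6 h, 108 at 8 h, 195 at 12 h, 17 at 16 h, 344 at 24 h, 478 at 36 h, 113 at 48 h and 76 at 60 h. Without the 2 broadest arrays the onset at 24 h held 427 probes, 331 of them the same, and that at 36 h held 425, 416 of them the same. Other onsets moved more in that setting, to 83 probes at 6 h (43 the same) and 175 at 60 h (74 the same). With only replicates 1 to 3 of 12 h and 24 h, rises began in 91 probes at 6 h, 57 at 8 h and 59 at 16 h. They began in 140 at 12 h (126 the same) and 334 at 24 h (260 the same). The times have 2, 3 or 6 arrays, so that counts of calls and onsets are not equally sensitive at all times. The onset times moved with the scaling as well. Quantile normalization widens the narrow early arrays and narrows the broad late ones, so that more early and fewer late onsets follow in part from it. After quantile normalization 773 of 1436 held rises began by 8 h, with 210 probes at 2 h (all 75 among them), 369 at 4 h, 119 at 6 h, 75 at 8 h, 78 at 12 h, 22 at 16 h, 146 at 24 h, 269 at 36 h, 132 at 48 h and 16 at 60 h. None of the 50 probes with onset at 6 h or the 108 at 8 h kept that onset. Held falls were 403 under that scaling, 175 of them by 8 h.

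The 75 probes that rose at 2 h had a median log ratio of 2.03 ± 0.31 (SD, n = 3) at 2 h, a 4.08-fold difference. It was 3.35 ± 0.049 (SD, n = 3) at 4 h, 4.07 ± 0.49 (SD, n = 3) at 36 h and 2.96 ± 0.86 (SD, n = 3) at 72 h. The 310 probes with onset from 4 to 8 h stood at 1.12 ± 0.13 (SD, n = 3) at 4 h, 1.97 ± 0.092 (SD, n = 6) at 12 h and 0.88 ± 0.45 (SD, n = 3) at 72 h. The 212 probes with onset at 12 or 16 h were highest at 36 h, with 2.77 ± 0.41 (SD, n = 3) against 0.70 ± 0.19 (SD, n = 3) at 8 h. The 344 probes with onset at 24 h went from 0.25 ± 0.083 (SD, n = 3) at 8 h to 1.36 ± 0.42 (SD, n = 6) at 24 h and 2.07 ± 0.37 (SD, n = 3) at 36 h. The 667 probes with onset from 36 to 60 h stood at 0.46 ± 0.3 (SD, n = 6) at 24 h and 1.66 ± 0.4 (SD, n = 3) at 60 h.

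Held falls were fewer than held rises. The 66 probes with a fall from 4 to 8 h had a median of 0.06 ± 0.34 (SD, n = 3) at 2 h, -1.09 ± 0.19 (SD, n = 3) at 4 h, -2.27 ± 0.41 (SD, n = 6) at 24 h and -2.85 ± 0.19 (SD, n = 3) at 72 h, 7.2-fold below the reference. The 69 probes with a fall at 24 h stood at -0.81 ± 0.18 (SD, n = 3) at 8 h and -2.18 ± 0.33 (SD, n = 3) at 36 h. Their number depended on which replicates of 12 h and 24 h were used: it was 13 with a replicate block, 13 with only replicates 1 to 3, 155 with only replicates 4 to 6. It was 35 after quantile normalization. Without the 2 broadest arrays the 308 rises and 879 falls at 72 h became 65 and 98, of which 13 and 93 were the same probes; after quantile normalization they were 10 and 34.

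**Figure D3:**
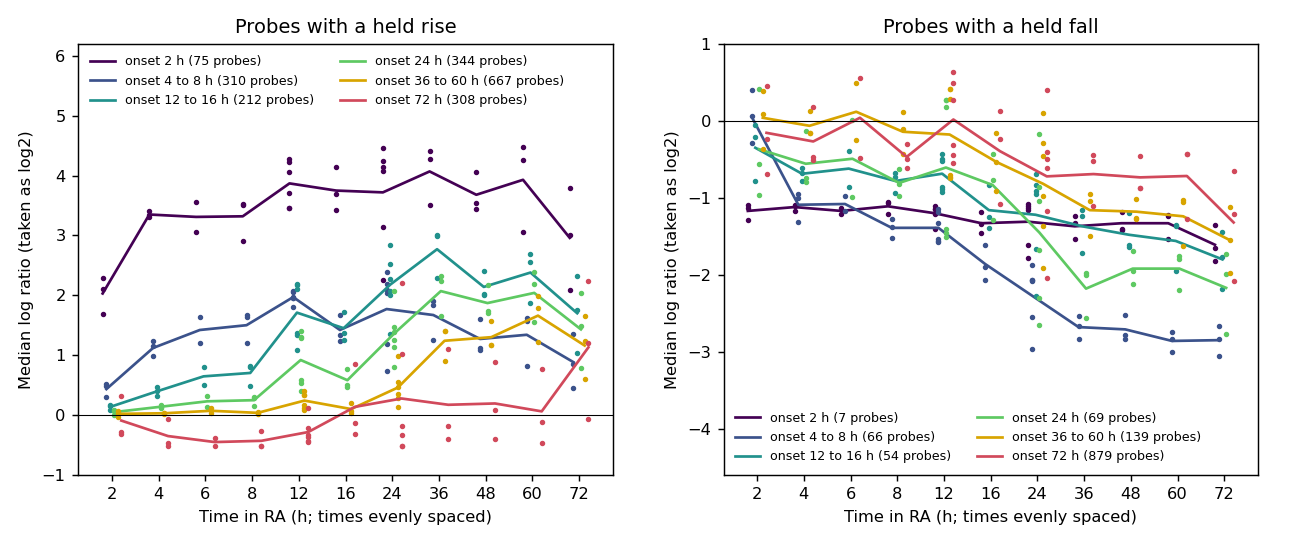
Median log ratio (taken as log2) of the probes of each onset group against time in RA in h, rises on the left and falls on the right, held except for those of 72 h, which has no next time; points are arrays and lines join the group means. The 75 probes with onset at 2 h go from 2.03 at 2 h to 4.07 at 36 h, and the 66 probes with a fall from 4 to 8 h reach -2.85 at 72 h.

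Successive times were compared to place changes within the course, free of the reference. From 2 h to 4 h, 13 probes fell, by a median of 1.25 on the log2 scale from 0.07 at 2 h to -1.18 at 4 h, and 1 rose. From 12 h to 16 h 10 probes fell, from 16 h to 24 h 1 rose, and from 36 h to 48 h 8 fell, by a median of 1.22 on the log2 scale. From 24 h to 36 h, 251 probes rose by a median of 1.09 and 5 fell; the median of the 251 was 0.44 at 24 h and 1.59 at 36 h. No probe was called between 4 and 6 h, 6 and 8 h, 8 and 12 h, 48 and 60 h or 60 and 72 h, where limma gave 246, 613, 8501, 1080 and 15941 probes at an unadjusted p under 0.05. With only replicates 4 to 6 at 12 h and 24 h, 624 probes were called from 8 to 12 h, 293 from 12 to 16 h and 401 from 16 to 24 h. With only replicates 1 to 3 there were 1, 18 and 140. Quantile normalization gave 177 from 2 to 4 h, 34 from 8 to 12 h and 307 from 12 to 16 h. The 256 calls from 24 h to 36 h were 79 after quantile normalization, 1167 with only replicates 1 to 3 at 24 h and 43 with only replicates 4 to 6, 434 without replicate 4 of 24 h, and 143 without replicate 2 or 77 without replicate 3 of 36 h. The counts of 14, 10, 1 and 8 also moved by more than 1.5 times without single arrays, between 2 and 33, 0 and 9, 0 and 46, and 0 and 10. Without replicate 3 of 60 h, 168 probes were called between 48 and 60 h and 671 between 60 and 72 h, and without replicate 3 of 72 h the latter count was 18211.

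The 72 h and 24 h samples were compared to ask which early responses were higher or lower at the end. Between them 628 probes were higher and 602 lower at 72 h, 235 and 159 with a difference of at least 1. The 235 had a median of 0.28 ± 0.16 (SD, n = 6) at 24 h and 1.75 ± 0.62 (SD, n = 3) at 72 h, and 152 of them were not called at 24 h. The 159 had a median of 1.67 ± 0.66 (SD, n = 6) at 24 h and 0.25 ± 0.48 (SD, n = 3) at 72 h, and 134 of them were called higher at 24 h. By onset of the rise, 2 of 75 probes from 2 h, 107 of 310 from 4 to 8 h, 20 of 212 from 12 or 16 h and 15 of 344 from 24 h were lower at 72 h than at 24 h. Of those 344, 15 were higher, as were 306 of the 667 from 36 to 60 h. The groups were defined on the same arrays. A rise from 36 to 60 h required no held call at 24 h, so that the number for that group follows in part from the definition. The total of 1230 was 775 and 782 without replicates 1 and 3 of 24 h, 24579 and 2303 without its replicates 5 and 6, 381 and 10461 without replicates 1 and 3 of 72 h, and 2491 without the 2 broadest arrays. After quantile normalization it was 348. With only replicates 1 to 3 at 24 h it was 36784 and with only replicates 4 to 6 it was 334. In 16 of 84 splits of these arrays, the real one included, at least as many probes were called, with 68336 the highest other. Chance was therefore not excluded for the total. The numbers by onset are those of the fit of all arrays and share this limit.

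The labels give 6 replicates only at 12 h and 24 h, which allows replicates 4 to 6 to be set against 1 to 3. At 12 h, 1742 probes were higher and 4366 lower in replicates 4 to 6. Of these probes, 803 of the 1742 (46.1%) and 883 of the 4366 (20.2%) were in an onset group. Among all 103446 probes the onset groups held 1916 rises and 1214 falls, so that both shares were well above the share over all probes. The groups were defined on the same arrays. Of the 344 probes with a rise at 24 h, 264 were higher in replicates 4 to 6, where their median was 1.33 ± 0.063 (SD, n = 3) against 0.51 ± 0.095 (SD, n = 3) in replicates 1 to 3; it was 1.29 ± 0.17 (SD, n = 3) in replicates 1 to 3 of 24 h. Of the 69 probes with a fall at 24 h, 61 were lower in replicates 4 to 6 (a group of 13 if replicates 1 to 3 alone are used), with a median of -1.46 ± 0.05 (SD, n = 3) against 0.24 ± 0.05 (SD, n = 3). The 310 probes with a rise from 4 to 8 h went both ways, 130 higher and 83 lower in replicates 4 to 6, with a median of 1.99 ± 0.064 (SD, n = 3) against 1.94 ± 0.12 (SD, n = 3). Of the 75 probes with onset at 2 h, 40 were lower in replicates 4 to 6, with a median of 3.54 ± 0.15 (SD, n = 3) against 4.19 ± 0.11 (SD, n = 3). At 24 h no probe was called between the sets, with 12754 at an unadjusted p under 0.05 in limma. The 12 h count was 3595 without replicate 2 and 4044 without replicate 5, and that at 24 h was 37956 without replicate 4.

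**Figure D4:**
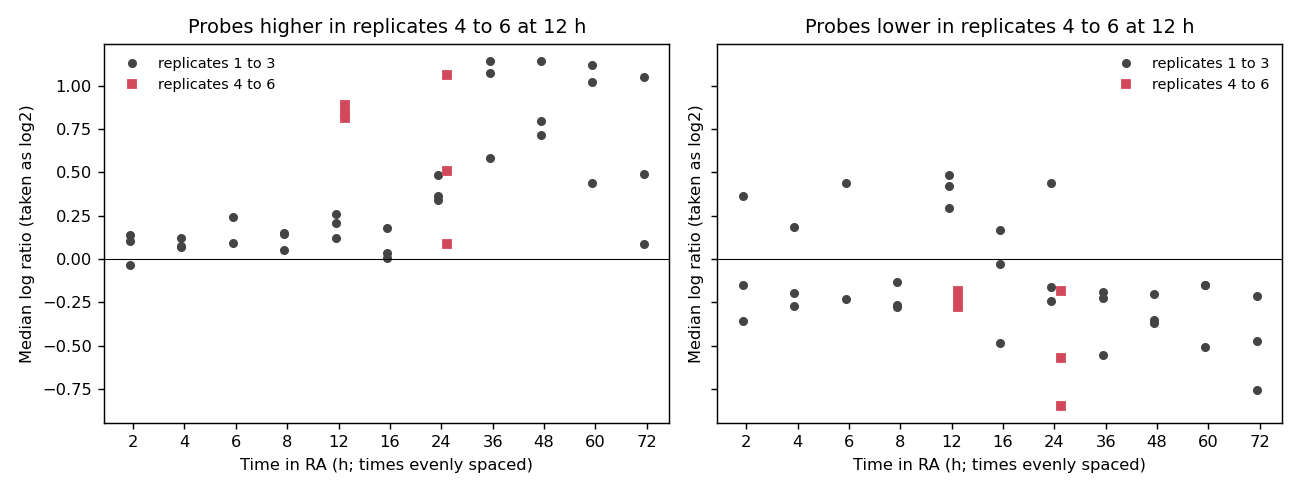
Median log ratio (taken as log2) in each array of the 1742 probes that were higher (left) and the 4366 that were lower (right) in replicates 4 to 6 than in 1 to 3 at 12 h, against time in RA in h; circles are replicates 1 to 3 and squares replicates 4 to 6. For the higher probes, replicates 4 to 6 at 12 h lie between 0.81 and 0.89 and replicates 1 to 3 between 0.12 and 0.26.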

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

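The tests on single arrays and on opposite directions below were chosen after the results were seen. At 24 h, replicate 5 stood apart from the other 5 arrays in the SD over probes, 0.779 against 0.325 to 0.463, and in the number of probes with a log ratio of at least 1 in size, 18993 against 1451 to 3129; chance gives such an array in about 1 of 20 groups. Of 24 such checks of the 12 h and 24 h arrays, 2 were met, both by this array. Another comparison of 72 h with 12 h called 28017 probes: 124 were higher than the reference at 12 h and lower at 72 h, and 6 were lower at 12 h and higher at 72 h. Without the 2 broadest arrays, 24 h replicate 5 and 72 h replicate 2, the numbers were 10231, 84 and 16.

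The 2 broadest arrays were compared with the others of their times. Their deviations from those arrays correlated with each other over probes (r = 0.856; probes are not independent replicates), and that of 24 h replicate 5 correlated with the deviation of 2 h replicate 2 as well (r = 0.663), which is consistent with a technical component shared by single arrays of different times. A more advanced response to RA is not borne out, since the deviation of the 72 h array had a correlation of -0.00594 with the change from 4 to 8 h to 48 to 60 h, and that of the 24 h array one of 0.198. A turned sign is not borne out either: of the 100 probes highest in the arrays of other times, 100% were above 0 in both arrays, and the slopes of the 2 arrays against the others of their times on the 75 probes with onset at 2 h were 0.602 and 0.668. The first component of the deviations from the group means, with 60.1% of their variance, was not confined to these 2 arrays. Its loadings, the weights of the arrays on it, were 0.549 and 0.313 for them. Arrays of other times had loadings too, such as 0.245 in 60 h replicate 3, 0.219 in 36 h replicate 1 and -0.171 in 16 h replicate 3. Leaving out the 2 broadest arrays may therefore not remove this component. Labelling, hybridisation and scaling by the authors stay open.

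Other splits of the same arrays were counted, as planned, for each comparison with at least 3 arrays on both sides, which leaves out the 2 steps that use the 2 arrays of 6 h. For 12 h against 16 h, 2 of 84 splits gave at least the 10 probes called, the highest other giving 500. That share was under 0.05, but several such tests were made with no allowance for their number. Leaving out replicate 1, 2 or 3 of 16 h gave 0 calls, so that the number is weak evidence against chance. Random assignment of the times to the 38 arrays gave as many probes as the 4529 that differed between RA times in 4 of 100 draws, the real one included, with 38221 the highest other. This share too was under 0.05 only without allowance for the number of tests. The share was above 0.05, and chance was not excluded, for 16 h against 24 h (1 probe, 8 of 84 splits as many, highest other 61758), 24 h against 36 h (256 probes, 9 of 84, highest other 65828) and 72 h against 24 h (1230 probes, 16 of 84, highest other 68336). Where no probe was called every split gives as many, so that the count tests nothing, as for 8 h against 12 h (84 of 84, highest other 623). Splits that call many times more probes than the real one point to a structure among the arrays that the times do not give. With 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real number and the highest of the other splits were 14 and 0 from 2 h to 4 h (1 split as many), 8 and 0 from 36 h to 48 h (1 split), 0 and 0 from 48 h to 60 h (10 splits), 0 and 37926 from 60 h to 72 h (10 splits), 6108 and 0 between the replicate sets at 12 h (1 split), and 0 and 0 between those at 24 h (10 splits).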

How the results depend on the processing

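Under eBayes with trend and robust options every total against the reference kept within 1.5 times its value (11 of 11). The 4 named probes kept their direction and their call in 60 of 60 comparisons of probe, time and setting. These covered 24 h and 72 h under a replicate block, median centring, neighbour subtraction and single arrays left out. The probes were picked for the smallest p of the F test on the same arrays, so that a kept call was likely from the start. Sizes could still move, as for probe 13378 at 24 h from -0.99 to -0.25 under neighbour subtraction. The cause of the changes that follow was not tested unless stated. Neighbour subtraction, leaving out the 2 broadest arrays, turning their sign, differences between RA times alone, both scalings for comparisons between times, median centring for the replicate sets, either replicate set for the steps from 8 h to 36 h and replicates 4 to 6 for 72 h against 24 h were chosen after seeing the data. Under median centring 19 of 25 totals kept within 1.5 times; the others were 45 from 2 to 4 h, 20 from 12 to 16 h, 9 from 16 to 24 h, 13 from 36 to 48 h, 30 from 48 to 60 h and 4 from 60 to 72 h. Parts of totals moved too: 1923 higher in place of 1181 at 16 h, 946 in place of 628 for 72 h against 24 h, and onset of rises in 491 in place of 308 probes at 72 h and 30 in place of 17 at 16 h. Fits of 1 time alone, which estimate the spread from 2 to 6 arrays, called 22, 1935, 0, 18204, 29473, 1700, 3441, 12498, 2053 and 1905 probes at 2, 4, 6, 8, 12, 24, 36, 48, 60 and 72 h. Quantile normalization gave 2877, 8709, 2917, 11413, 21541, 8626 and 6430 at 2, 4, 6, 8, 12, 48 and 72 h, 177 from 2 to 4 h, 34 from 8 to 12 h, 307 from 12 to 16 h, 7 from 16 to 24 h, 79 from 24 to 36 h, 5 from 36 to 48 h, 2 from 48 to 60 h, 348 for 72 h against 24 h, and there a share of 67% higher in place of 51.1%. Array weights gave 2604, 8349, 3766, 43959, 40719, 60711, 22929, 64961 and 9900 at 2, 4, 6, 8, 12, 24, 36, 60 and 72 h. The size threshold of 1 leaves fewer probes by construction: 88, 286, 352, 471, 847, 642, 1104, 1807, 1720, 2054 and 2582 from 2 h to 72 h, 2 from 12 to 16 h, 149 from 24 to 36 h and 5 from 36 to 48 h. The replicate numbers did not pair the arrays: deviations of arrays with the same number at different times correlated by -0.0165 on average, from -0.824 to 0.787, against 0.00994 for different numbers. With a replicate block the count was 3250 at 24 h, 42 from 2 to 4 h, 4 from 8 to 12 h, 52 from 12 to 16 h, 0 from 16 to 24 h, 1075 from 24 to 36 h and 5708 for 72 h against 24 h, and none of the 16 other totals moved by more than 1.5 times. Onset of falls did: 7 in place of 22 probes at 8 h, 0 in place of 3 at 12 h, 29 in place of 51 at 16 h, 13 in place of 69 at 24 h and 179 in place of 83 at 36 h. With only replicates 1 to 3 at 12 h and 24 h it was 2791 at 12 h, 3338 at 24 h, 1, 18, 140 and 1167 for the steps from 8 h to 36 h, and 36784 for 72 h against 24 h; with only replicates 4 to 6 it was 42134 at 24 h, 624, 293, 401 and 43 for those steps, and 334. Neighbour subtraction gave 363 at 2 h, 768 at 4 h, 40 from 2 to 4 h, 36 from 12 to 16 h, 19 from 16 to 24 h, 13 from 36 to 48 h, 68 from 48 to 60 h, 4 from 60 to 72 h and 2839 for 72 h against 24 h. Without the 2 broadest arrays there were 2566, 8190, 4543, 11732 and 22034 at 8, 12, 16, 60 and 72 h, 62 from 2 to 4 h, 183 from 12 to 16 h, 117 from 16 to 24 h, 422 from 24 to 36 h, 20 from 36 to 48 h, 118 from 48 to 60 h, 3 from 60 to 72 h and 2491 for 72 h against 24 h. Turning their sign, against the direction of the highest probes in them, gave 4059 at 24 h, 271 at 72 h, and 1 each from 24 to 36 h, from 60 to 72 h and for 72 h against 24 h. Differences between RA times alone gave 4529 of the 20518 probes called at any time. Leaving out 1 array moved 60 of 167 counts by more than 1.5 times. The ranges were 506 (without replicate 1) to 657 at 2 h, 371 to 391 at 6 h (both arrays), 992 (without replicate 2) to 1496 at 8 h, 1541 (without replicate 1) to 3242 at 16 h, 4131 (without replicate 6) to 10565 (without replicate 2) at 24 h, 3750 (without replicate 3) to 4750 at 36 h, 3662 (without replicate 2) to 3911 at 48 h, 4242 (without replicate 1) to 7915 at 60 h, and 12678 (without replicate 2) to 52762 (without replicate 3) at 72 h, where replicate 1 left out gave 19684. Between times they were 2 to 33 from 2 to 4 h (all 6 arrays), 0 to 8 from 4 to 6 h and from 6 to 8 h (either array of 6 h), 0 to 7 from 8 to 12 h (replicate 1 of 12 h), 0 to 9 from 12 to 16 h (all arrays but replicate 1 of 12 h), 0 to 46 from 16 to 24 h (all but replicate 3 of 24 h), 77 to 434 from 24 to 36 h (replicate 3 of 36 h and replicate 4 of 24 h; 143 without replicate 2 of 36 h), 0 to 10 from 36 to 48 h (all but replicate 1 of 36 h), 0 to 168 from 48 to 60 h (replicate 3 of 60 h), 0 to 18211 from 60 to 72 h (replicate 3 of 72 h; 671 without replicate 3 of 60 h) and 381 to 24579 for 72 h against 24 h (replicate 1 of 72 h and replicate 5 of 24 h). At any time they were 16759 to 32313 (replicate 5 of 24 h), and between the replicate sets 3595 (replicate 2; 4044 without replicate 5) to 6586 at 12 h and 0 to 37956 (replicate 4) at 24 h. Filters on dim probes, gene-level means, Hox onset, windows and gene lists were not run, as the ratios carry no brightness and the probes no names. Signal over background, and what it limits, was not measured.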

Other observations

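The tests in this part were chosen after the results were seen. Of the 1742 probes that were higher in replicates 4 to 6 than in replicates 1 to 3 at 12 h, 158 belong to the 212 probes with a held rise at 12 or 16 h and 226 to the 667 with a rise from 36 to 60 h. Their median log ratio was 0.12 ± 0.056 (SD, n = 3) at 8 h, 0.2 ± 0.069 (SD, n = 3) in replicates 1 to 3 of 12 h and 0.85 ± 0.037 (SD, n = 3) in replicates 4 to 6 of 12 h. It was 0.07 ± 0.094 (SD, n = 3) at 16 h, 0.4 ± 0.076 (SD, n = 3) in replicates 1 to 3 of 24 h, 0.55 ± 0.49 (SD, n = 3) in replicates 4 to 6 of 24 h and 0.93 ± 0.3 (SD, n = 3) at 36 h. The course was thus not a steady rise. For the 4366 probes that were lower in replicates 4 to 6, it was replicates 1 to 3 of 12 h that stood apart from the 8 h arrays: their median was -0.225 ± 0.08 (SD, n = 3) at 8 h, 0.4 ± 0.097 (SD, n = 3) in replicates 1 to 3 and -0.228 ± 0.046 (SD, n = 3) in replicates 4 to 6 of 12 h, -0.116 ± 0.34 (SD, n = 3) at 16 h and -0.323 ± 0.2 (SD, n = 3) at 36 h. At 24 h the median of these 4366 was 0.0116 ± 0.37 (SD, n = 3) in replicates 1 to 3 and -0.531 ± 0.33 (SD, n = 3) in replicates 4 to 6. Single arrays of other times reached the level of replicates 1 to 3 of 12 h, such as 0.438 in 6 h replicate 3 and 0.439 in 24 h replicate 2.

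A candidate explanation for these 1742 probes is a more advanced RA response in replicates 4 to 6: 92.7% of them were higher at 36 h than at 8 h, against 49.2% of all probes, in arrays that had no part in the 12 h comparison. For the 4366 probes that were lower in replicates 4 to 6, the same idea in the form of a lasting fall is not borne out. Of them, 55.5% were lower at 36 h than at 8 h, against 50.8% of all probes. That comparison cannot decide about a change that had passed by 36 h. Only 11% of them were lower in replicates 1 to 3 of 24 h than at 8 h. The median of these 4366 probes ranged over 0.76 among the 12 h arrays. Only 1 of the 10 other times spanned as much (24 h, 1.28, with 6 arrays where most times have 3). With fewer arrays, 2 h came near it, from -0.354 to 0.365, as did 6 h, from -0.23 to 0.438. A component that also separates arrays of a single time elsewhere therefore stays open. Whether the sets differ in the same way at 24 h stays open too: in replicates 4 and 6 against 1 to 3, 81.1% of the 1742 were higher and 90.6% of the 4366 lower (r = 0.488 with the 12 h difference over all probes), but 7 and 6 of the 10 splits of those 5 arrays gave as high a share, up to 96.6% and 95.8%. Separate culture series, a labelling error and hybridisation batches stay open, since the labels name none.

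The 649 probes called lower at 2 h lay together on the array, if probe numbers follow its lines of 199 spots: 96.3% of them had another of the 649 among the nearest spots, against at most 19.1% in 1000 random sets and 1.34% of the 149 probes called higher. The line length was chosen on the same values, and the random sets did not repeat that choice. The grouping may reflect a blemish on the array of the shared reference, as 78.4% of the 649 were below 0 in all 38 arrays. That share follows in part from how the probes were picked. The 3 arrays of 2 h gave the mean, and the other arrays entered the pooled spread, so that probes with little variation were favoured. Lower transcript levels are an unlikely source of the grouping, since only 3.03% of the 66 probes with a held fall from 4 to 8 h had another of their kind among the nearest spots, where random sets reached 13.6%. After neighbour subtraction 206 of the 649 and 110 of the 149 were still called in the same direction. Of those 206, 193 were among the 625 probes that had another of the 649 nearby, so that they are not free of the grouping. A lower transcript level stays open for the 206.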
